A study of Mus musculus with 10 samples.

How the data were processed

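Total RNA was sequenced from CD31-positive cells sorted with magnetic beads from B16F10 tumours. B16F10 is a mouse melanoma cell line that grows as a pigmented tumour in C57BL/6 mice. Cells carrying CD11b, a myeloid surface protein, were depleted before the CD31 selection, per the labels' protocols. Libraries were made with a stranded total RNA kit after removal of ribosomal RNA, per the labels' protocols. The strain label of the wild-type libraries names an inducible Cre recombinase driven by Cdh5, a gene active in endothelium. That of the inactivated group adds a floxed Shb gene.

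The deposited values are FPKM per gene symbol, which scales fragments by transcript length and by the mapped fragments of the library. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1 and the GRCm38 build. The annotation the authors used, and whether their counting used strand, are not given in the sources used here. Each of the 10 deposited FPKM files held the same 28454 gene symbols, with a comma as the decimal mark, and each was read as a decimal number. FPKM keeps no read totals, so the depth per sample is unknown. The most common low value of receptor genes, a rough sign of what 1 fragment is worth, was 0.1 in wild-type replicate 1 and 0.07 in Shb-inactivated replicate 2. It was 0.01 to 0.03 in the other libraries, so low genes are the least precise in those 2 libraries. Some exact zeros are likely failed estimates, since the abundant genes Igfbp3 and Rn7sk were listed at 0 in 1 library each and mt-Co1 in 6. For such genes each library's value is given.

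Values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 4 of the 10 libraries were tested, 12805 in all. The 4 wild-type and 6 Shb-inactivated libraries were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no covariate, two-sided. Benjamini-Hochberg adjusted p-values under 0.05 counted as past the threshold. Fold changes are Shb-inactivated minus wild-type on the log2(FPKM + 1) scale, which understates changes of low genes. The series text gives 4 and 6 mice, and p-values measure the spread between these libraries. Single genes were also tested by an exact permutation test over all 210 splits of 10 libraries into 4 and 6.

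Lists of genes fixed before the data were examined numbered 39, and 33 had at least 5 tested members. They were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation, fry and an exact permutation test of each list's mean log2 value were alternatives. The last was added after the data were seen. For 16 lists of cell type markers, the mean log2(FPKM + 1) of all members served as a score per library and was compared by the exact permutation test. Some genes stand on more than 1 list.

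The genes named were set by a rule fixed in advance. It took Shb, Shd, She and Shf; genes past the threshold; and the sort markers Pecam1, Cdh5 and Itgam. With fewer than 5 genes past the threshold it added the 10 genes per direction with the smallest unadjusted p and a mean of at least 1 FPKM, leaving out clone-type symbols. From each list without a member past the threshold it took the 2 with the highest mean FPKM, as values. Gene positions came from GENCODE vM21 on GRCm38, in which 25987 of the 28454 symbols were found.

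Alternatives changed the pseudocount, the filter, the scaling, the weights, the test, the covariates and the libraries used, with each library also left out in turn. Alternatives added after the data were seen left out 3 libraries rich in myeloid transcripts or 3 low in small RNAs, treated zeros in abundant genes as missing, or used other covariates. The limma and camera steps were tested on simulated data of 12805 genes with independent noise for this comparison. They recovered 64% of genes shifted by log2 1 and 84% of those shifted by log2 2, with 6 wrong calls among 154. These rates hold for 200 seeded genes with independent noise and do not show what the real comparison could detect. Camera gave an adjusted p of 2.77e-26 for a shifted list and 0.924 for an unshifted one. Genes in real lists vary together, which the simulation left out. Plots were drawn with matplotlib 3.10.9.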

Results

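Gene expression was measured in CD31-positive cells isolated from B16F10 melanomas. The tumours had grown in wild-type mice (4 libraries) or in mice with Shb conditionally inactivated in endothelium (6 libraries). Shb encodes an adaptor protein with an SH2 domain that acts downstream of VEGF receptor 2 and other tyrosine kinase receptors. The comparison asks how loss of endothelial Shb changes the transcripts of tumour endothelium. Values are FPKM, whose sum per library ran from 477329 to 576687, and sequencing depth is unknown. Spearman correlations between libraries were 0.841 to 0.977, and no libraries were identical.

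Shb itself was lower in the inactivated group. Its mean was 3.68 ± 1.19 FPKM (SD, n = 4) in wild-type libraries and 0.942 ± 0.414 (SD, n = 6) in Shb-inactivated libraries. The mean left was 25.6% of the wild-type mean, a 3.91-fold difference. The highest inactivated library had 1.44 FPKM and the lowest wild-type library 2.78. The log2 fold change was -1.27 (SE 0.21, 95% interval -1.73 to -0.81). Its exact permutation p was 0.00476, the smallest that 210 splits can give, and it ranked first by unadjusted p among 12805 genes. Its limma p adjusted over all genes was 0.989. The gene lies on chromosome 4 from 45423278 to 45532470 on the minus strand in GRCm38 (ENSMUSG00000044813.15). Gene-level FPKM also counts exons outside a deleted part, which the labels do not name. Without 3 libraries low in small RNAs the log2 fold change was -1.19, and the other 3 libraries, 1 against 2, were too few to test. Pseudocount 5 gave -0.54 and pseudocount 0.1 gave -1.92. Of the related adaptors, She was 24.2 ± 2.22 FPKM (SD, n = 4) and 31.8 ± 3.48 (SD, n = 6), with an exact permutation p of 0.00476 and an adjusted limma p of 0.989. Its log2 fold change of 0.38 was close to the median of 0.34 of the pan-endothelial genes given below. Shf was 3.22 and 3.67 FPKM, and Shd was 0.15 and 0.0883 FPKM.

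**Figure D1:**
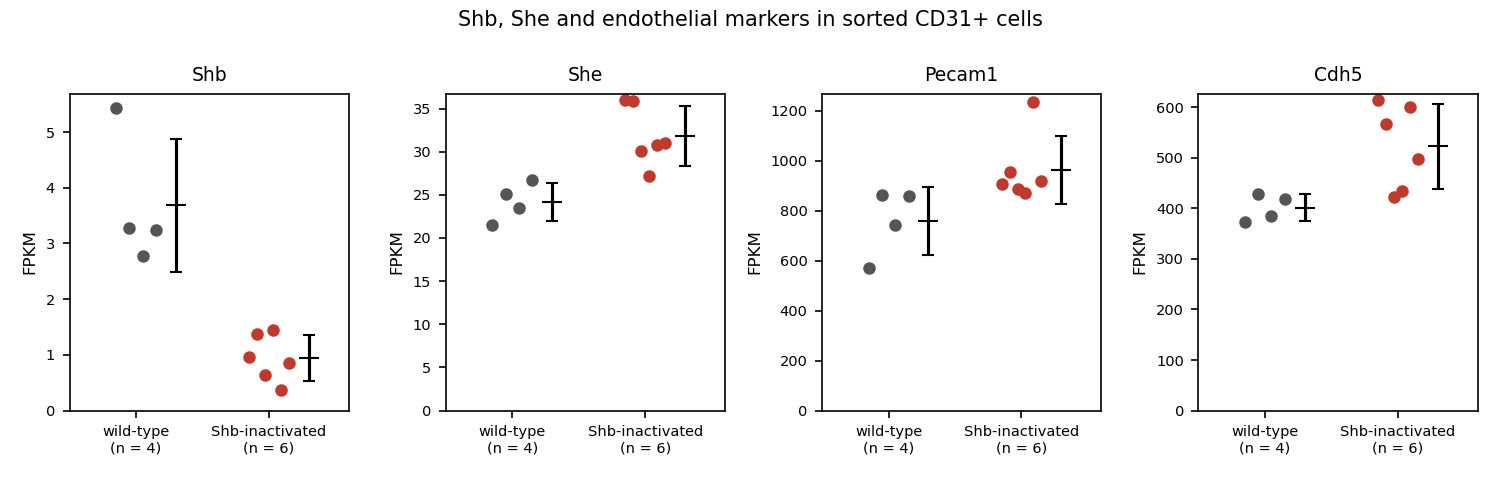
FPKM of Shb, She, Pecam1 and Cdh5 per library (points), with mean and SD (bars) for 4 wild-type and 6 Shb-inactivated libraries. All inactivated libraries had at most 1.44 FPKM of Shb and all wild-type libraries at least 2.78.

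Endothelial transcripts were slightly higher in the Shb-inactivated libraries, without any 1 gene past the threshold. All 31 genes of the pan-endothelial list had a fold change above 0, with a median log2 fold change of 0.34. Pecam1, the gene for the sorted surface protein CD31, was 759 ± 138 FPKM (SD, n = 4) and 963 ± 137 (SD, n = 6). Cdh5, which encodes VE-cadherin, was 402 ± 26.3 and 523 ± 83.9 FPKM, and Egfl7 was 590 and 654 FPKM. Camera gave the list an adjusted p of 3.58e-13, and an adjusted p = 0.292 with an estimated correlation. Without wild-type replicate 1 the median was 0.22. With the melanoma marker score as a covariate it was 0.16, and without the 3 libraries low in small RNAs also 0.16. It was 0.19 with library quality weights and 0.14 with the melanoma and macrophage scores. The mean log2 score of the list was 6.93 and 7.26 (exact permutation p = 0.0524, adjusted 0.356).

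Lists of vessel subtypes lay in the same direction. Tip cell genes had a median of 0.33, with 19 of 21 members above 0. Esm1, a secreted proteoglycan of sprouting endothelium, was 773 ± 351 and 1058 ± 695 FPKM, and 773 and 780 FPKM without Shb-inactivated replicate 5. Igfbp3, an insulin-like growth factor binding protein, was listed at 0 in Shb-inactivated replicate 5. It was 2059, 3356, 2804 and 3015 FPKM in wild-type replicates 1 to 4 and 3248, 3713, 3891, 4235 and 3542 FPKM in the other inactivated libraries. Venous genes had a median of 0.35, with Ctla2a at 518 and 692 FPKM (518 and 520 without Shb-inactivated replicate 5) and Aplnr, the apelin receptor, at 110 and 156 FPKM. Without wild-type replicate 3 that median was 0.60. Arterial genes had a median of 0.24, with the Notch ligand Dll4 at 86.9 and 114 FPKM and Notch4 at 78.6 and 99.0 FPKM. Adjusted over the list alone, 1 arterial gene passed, the transcription factor Sox17, and no gene passed in any other list. The arterial median was 0.15, 0.11, 0.15 and 0.15 without wild-type replicate 3 and Shb-inactivated replicates 2, 5 and 6. Lung capillary genes had a median of 0.28, with Gpihbp1 at 836 and 1125 FPKM and Apln at 440.2 and 539 FPKM (513 and 539 without wild-type replicate 3, 440.2 and 468 without Shb-inactivated replicate 5). Junction genes had a median of 0.20, with Ctnnb1, encoding beta-catenin, at 506 and 581 FPKM. Leukocyte adhesion genes had a median of 0.18, with Cd34 at 547 and 650 FPKM (610 and 650 without wild-type replicate 1). The chemokine Ccl2 was 288 and 265 FPKM, and 49.4 and 265 without wild-type replicate 3. With Shb-inactivated replicates 3 and 4 left out as well, which are also rich in myeloid transcripts, Ccl2 was 49.4 and 24.5 FPKM. Among the libraries left, wild-type replicates 1 and 2 still had more myeloid transcripts than the rest. The leukocyte adhesion median was 0.09, 0.35 and 0.29 without wild-type replicates 1, 3 and 4. Without the 3 libraries low in small RNAs the tip cell, arterial and junction medians were 0.16, 0.05 and 0.06, and the arterial call was lost. The tip cell, arterial, lung capillary, leukocyte adhesion and junction medians were 0.09, 0.15, 0.12, 0.29 and 0.09 with the melanoma score as a covariate, 0.06, 0.12, 0.17, 0.33 and 0.06 with library quality weights, and 0.15, 0.17, 0.12, 0.21 and 0.13 with both marker scores. The arterial and lung capillary calls were lost in all 3, and the leukocyte adhesion call with the melanoma score and with both scores. The arterial and leukocyte adhesion medians were 0.14 and 0.27 with the macrophage score and 0.11 and 0.11 with the replicate block. Without the 3 libraries rich in myeloid transcripts (wild-type replicate 3 and Shb-inactivated replicates 3 and 4) the arterial, venous and leukocyte adhesion medians were 0.36, 0.58 and 0.29. These 6 lists passed camera at the preset correlation, and their adjusted p-values with an estimated correlation were 0.292 to 0.447. The 4 tested lymphatic genes were too few for camera. Flt4 was 46.2 and 58.1 FPKM, and Lyve1 was 24.3 and 22.7 FPKM (3.86 and 22.7 without wild-type replicate 3). Without all 3 libraries rich in myeloid transcripts Lyve1 was 3.86 and 4.005 FPKM. The lymphatic score differed by 0.09 (exact permutation p = 0.581), and by 0.0033 without Shb-inactivated replicate 5.

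Genes of the VEGF receptor pathway in which Shb acts had a median log2 fold change of 0.20, with 19 of 27 above 0. Kdr, encoding VEGF receptor 2, was 342 ± 84.2 and 411 ± 79.3 FPKM, and Flt1, encoding VEGF receptor 1, was 306 ± 41.7 and 413 ± 106 FPKM. Camera gave an adjusted p of 0.00392, and an adjusted p = 0.292 with an estimated correlation. Without wild-type replicate 1 the median was 0.13, and without the 3 libraries low in small RNAs 0.07. It was 0.09 with the melanoma score, 0.09 with library quality weights and 0.12 with both marker scores, and the call was lost under quantile normalization (0.15). The Notch list had a median of 0.24 and a camera adjusted p of 0.0455, with an adjusted p = 0.52 with an estimated correlation. The call was lost without any of wild-type replicates 1 to 4 (medians 0.21, 0.26, 0.16 and 0.25) or Shb-inactivated replicates 1, 2 and 6 (0.11, 0.11 and 0.23). Without the 3 libraries low in small RNAs the direction turned (median -0.01). The call was also lost at a mean of at least 5 FPKM, under TPM and quantile scaling, with library quality weights (0.12), and with the melanoma score (0.15), the macrophage score (0.18) or the small-RNA class (0.19) as a covariate. The Notch score was 4.59 and 4.69 in Shb-inactivated replicates 1 and 2, which are low in small RNAs, 4.08 to 4.29 in the other inactivated libraries and 4.14 to 4.29 in wild-type libraries. Basement membrane genes had a median of 0.20, with Sparc at 1823 and 2413 FPKM and Thbs1 at 469 and 506 FPKM (522 and 506 without wild-type replicate 4, 469 and 424 without Shb-inactivated replicate 5). Their adjusted p was 0.00632, and 0.413 with a median of 0.09 without wild-type replicate 3; it was an adjusted p = 0.52 with an estimated correlation. Their median was 0.12, 0.34 and 0.32 without Shb-inactivated replicates 2, 3 and 4. The call was also lost without the 3 libraries low in small RNAs (median 0.09), with the melanoma score as a covariate (0.10), with library quality weights (0.14), with the replicate block (0.18) and under quantile normalization (0.20). With the macrophage score the median was 0.11. Genes of TGF-beta signalling and endothelial-mesenchymal transition did not pass (median 0.07, adjusted p 0.171). They passed without Shb-inactivated replicate 3 (0.16, adjusted p 0.0361) and with no filter (0.09, adjusted p 0.0354), and the median turned without Shb-inactivated replicate 2 (-0.0003) or the 3 libraries low in small RNAs (-0.0042). Vim was 2007 and 2447 FPKM, and Ctgf was 213 and 304 FPKM (213 and 221 without Shb-inactivated replicate 5).

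**Figure D2:**
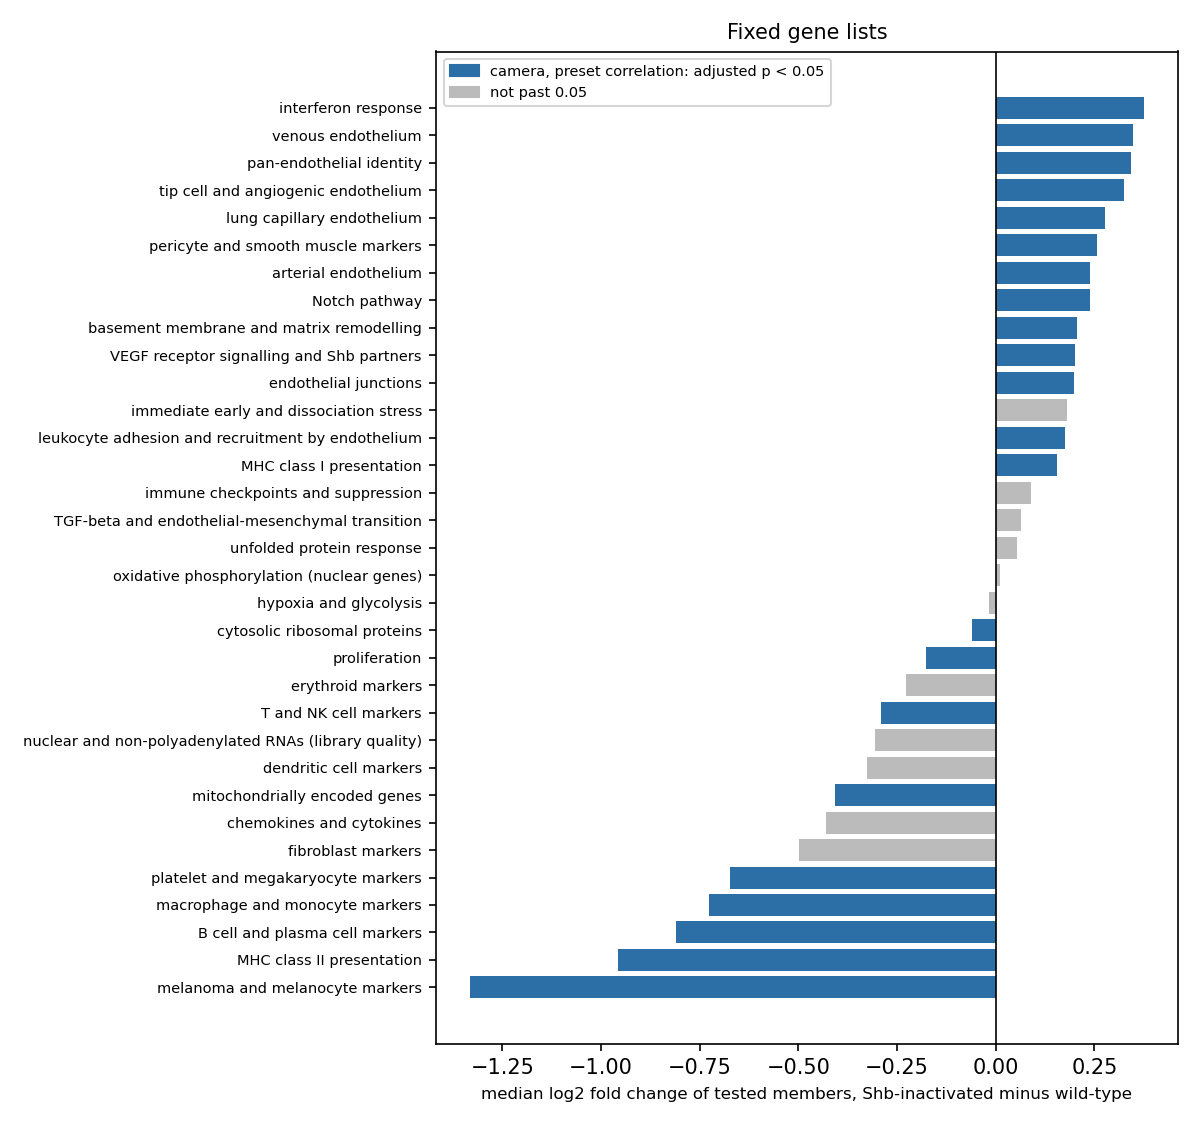
Median log2 fold change (Shb-inactivated minus wild-type) of the tested members of 33 fixed gene lists. Blue bars passed camera at the preset correlation (22 lists, 13 higher and 9 lower), and none passed with an estimated correlation.

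Interferon response genes were higher by a median of 0.38, with 28 of 30 above 0, but not in every inactivated library. The list's mean log2 score was 3.53 to 3.62 in wild-type replicates 1, 2 and 4 and 4.77 in replicate 3. It was 3.63 and 3.59 in Shb-inactivated replicates 1 and 2 and 4.35 to 4.88 in replicates 3 to 6 (exact permutation p = 0.371). Bst2, an antiviral membrane protein, was 144 and 166 FPKM, and Ifi27l2a was 124 and 68.6 FPKM. Wild-type replicate 3, rich in myeloid transcripts, had 440 FPKM of Ifi27l2a, and without it the means were 18.5 and 68.6 FPKM. Shb-inactivated replicates 3 and 4, also rich in them, had 202 and 151 FPKM, and the other inactivated libraries 9.66 to 19.6. The list had a camera adjusted p of 5.72e-07, and an adjusted p = 0.517 with an estimated correlation. Its median was 0.69 without wild-type replicate 3 and 0.20 without Shb-inactivated replicate 5. It was 0.17 with the replicate block, 0.22 with both marker scores, 0.56 without the 3 libraries rich in myeloid transcripts and 0.61 without the 3 low in small RNAs. MHC class I genes had a median of 0.15, with B2m at 1486 and 1871 FPKM (1486 and 1575 without Shb-inactivated replicate 5) and H2-D1 at 379 and 431 FPKM. Their adjusted p was 0.00412, and an adjusted p = 0.526 with an estimated correlation. The class I call was lost without wild-type replicate 2 (median 0.09) or 4 (median 0.07). It was also lost with the replicate block (0.06) and with both marker scores (0.10). Its median was 0.35 without wild-type replicate 3, 0.09 without Shb-inactivated replicate 5, 0.31 with library quality weights and 0.48 without the 3 libraries rich in myeloid transcripts.

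MHC class II and B cell transcripts were lower in the Shb-inactivated libraries. All 11 class II genes had a fold change below 0, with a median of -0.96. Cd74, the invariant chain, was 242 ± 221 and 81.5 ± 43.3 FPKM, and Ctss was 229 and 163 FPKM. Without wild-type replicate 3 the wild-type means were 132 FPKM of Cd74 and 47.9 of Ctss, so the direction of Ctss turned. Without all 3 libraries rich in myeloid transcripts Cd74 was 132 and 86.8 FPKM and Ctss 47.9 and 13.1 FPKM. Among the libraries left, the macrophage score was 3.28 and 3.99 in wild-type replicates 1 and 2. That score was 1.54 in wild-type replicate 4 and 1.57 to 1.94 in the inactivated libraries, so myeloid transcripts were still unequal. The class II list was the one with an exact permutation p under 0.05 for its score (p = 0.0381, adjusted 0.52 over all lists). All 13 B cell and plasma cell genes were below 0, with a median of -0.81. Ighm, the IgM heavy chain, was 40.4 ± 12.8 and 19.7 ± 12.5 FPKM, and Igkc was 59.7 ± 27.7 and 29.0 ± 27.5 FPKM. All 14 T and NK cell genes were below 0, with a median of -0.29. Lck was 6.00 and 5.57 FPKM and Cd2 was 5.98 and 3.13 FPKM. Lck turned without wild-type replicate 1 (5.34 and 5.57 FPKM), without Shb-inactivated replicate 3 (6.00 and 6.21 FPKM) and without the 3 libraries rich in myeloid transcripts (6.75 and 6.90 FPKM). The T and NK call was lost without wild-type replicate 1 (median -0.10), without the 3 libraries rich in myeloid transcripts (-0.16, adjusted p 0.0769), with the melanoma score (-0.21, adjusted p 0.0521) and with both marker scores (-0.09, adjusted p 0.167). Its median was -0.46 and -0.19 without wild-type replicate 3 and Shb-inactivated replicate 3, and -0.15 under quantile normalization. With pseudocounts of 0.1 and 5 the B cell median was -1.28 and -0.39 and the T and NK median -0.56 and -0.11. Camera adjusted p-values were 1.53e-08, 3.14e-11 and 0.000639. With an estimated correlation the 3 lists had an adjusted p = 0.292, 0.292 and 0.52. Immune checkpoint genes did not pass (adjusted p 0.283), with a median of 0.09 and a mean of -0.11. They passed without wild-type replicate 3 (0.38, adjusted p 0.0177), and the median turned without wild-type replicates 2 or 4 or Shb-inactivated replicate 4 (-0.07, -0.16 and -0.03), without the 3 libraries low in small RNAs (-0.05) and with no filter (-0.10). Lgals1 was 500.0 and 455 FPKM (372 and 455 without wild-type replicate 3) and Entpd1 was 88.7 and 114 FPKM. Shb-inactivated replicates 3 and 4 had 732 and 755 FPKM of Lgals1, and the other inactivated libraries 253 to 350. Chemokines and cytokines did not pass (median -0.43, adjusted p 0.469), with Cxcl2 at 350.4 and 140.1 FPKM. Both turned without wild-type replicate 3, to a median of 0.48 and to 40.3 and 140.1 FPKM of Cxcl2. Shb-inactivated replicates 3 and 4 had 397 and 399 FPKM of Cxcl2, and the other inactivated libraries 4.42 to 18.4. Without all 3 libraries rich in myeloid transcripts the list passed (median -0.74, adjusted p 0.0161), with myeloid transcripts still unequal as above. The median also turned with library quality weights (0.19), the melanoma score (0.25), the macrophage score (0.13) and the replicate block (0.05). Dendritic cell genes did not pass (median -0.33, adjusted p 0.0609), with Cst3 at 280.3 and 291 FPKM and Zbtb46 at 15.9 and 17.2 FPKM. Their median was -0.10, -0.08 and -0.17 without wild-type replicates 1 and 3 and Shb-inactivated replicate 3, and -0.15, -0.07, -0.09 and -0.06 without the 3 libraries low in small RNAs, with library quality weights, with the melanoma score and with both scores. They passed without wild-type replicate 4 (-0.37, adjusted p 0.0390), Shb-inactivated replicate 1 (-0.34, adjusted p 0.0442) or 2 (-0.41, adjusted p 0.0430), under TPM scaling (-0.30, adjusted p 0.0343), with the macrophage score (-0.34, adjusted p 0.0175) and with the small-RNA class (-0.41, adjusted p 0.0467).

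Markers of other cells varied between libraries within each group. Melanoma genes were lower in the Shb-inactivated group, with 15 of 16 below 0 and a median of -1.33. Dct and Tyrp1, enzymes of melanin synthesis, were 156 ± 178 and 41.6 ± 47.4 FPKM, and 122 ± 144 and 28.8 ± 28.5 FPKM. They were 68.9 and 41.6, and 50.1 and 28.8 FPKM, without wild-type replicate 1. Without wild-type replicate 1, which had 419 FPKM of Dct, the median was -0.80, and it was -0.57 without the 3 libraries low in small RNAs, -0.47 with library quality weights and -0.74 with a pseudocount of 5. Camera gave an adjusted p of 3.33e-08, and an adjusted p = 0.351 with an estimated correlation. Itgam, the gene for the depleted CD11b protein, was 109 FPKM in wild-type replicate 3, 29.3 in Shb-inactivated replicate 3 and 35.9 in replicate 4. It was at most 5.85 FPKM elsewhere. Lyz2, a myeloid lysozyme, was 2944, 2264 and 1577 FPKM in those 3 libraries. It was 107 and 292 FPKM in wild-type replicates 1 and 2 and 16.9 to 28.7 FPKM in the rest. Leaving out the 3 libraries therefore did not even out myeloid transcripts between the groups. Macrophage genes had a median of -0.73 (adjusted p 0.0334, and p = 0.627 with an estimated correlation, adjusted). The call was lost without wild-type replicate 3 (median 0.38) or Shb-inactivated replicates 1, 2, 5 and 6 (-0.41, -0.33, -0.32 and -0.33). The median was -1.61, -1.47 and -1.45 without wild-type replicate 4 and Shb-inactivated replicates 3 and 4. The median turned with library quality weights (0.22), the melanoma score (0.62) and the replicate block (0.26). The call was also lost without the 3 libraries low in small RNAs (-0.18), with the small-RNA class (-0.55), with no filter, under median-of-ratios scaling and with a pseudocount of 5. Without the 3 libraries rich in myeloid transcripts the median was -1.26. C1qa was 165 and 155 FPKM, and 23.3 and 155 FPKM without wild-type replicate 3. Without all 3 libraries rich in myeloid transcripts C1qa was 23.3 and 2.03 FPKM. Platelet genes had a median of -0.67, with Pf4 at 296 and 196 FPKM and Itgb3 at 60.8 and 71.4 FPKM, or 69.3 and 71.4 without wild-type replicate 3 (adjusted p 5.28e-05, and adjusted p = 0.393 with an estimated correlation). Pf4 turned without wild-type replicate 3, to 86.2 and 196 FPKM, and without all 3 libraries rich in myeloid transcripts it was 86.2 and 27.9 FPKM. With pseudocounts of 0.1 and 5 the platelet median was -1.22 and -0.35. Pericyte genes had a median of 0.26, with Rgs5 at 70.9 and 104 FPKM and Abcc9 at 45.1 and 76.3 FPKM. Their adjusted p was 0.0403, and an adjusted p = 0.627 with an estimated correlation. The call was lost without wild-type replicates 1 or 3 (medians 0.09 and 0.02) or Shb-inactivated replicates 2, 5 and 6 (0.15, 0.06 and 0.15). Without wild-type replicates 2 or 4 or Shb-inactivated replicates 3 or 4 the medians were 0.41, 0.46, 0.45 and 0.46. The direction turned with library quality weights (median -0.22), with the melanoma score as a covariate (-0.26), with both marker scores (-0.16) and with the replicate block (-0.10). The call was also lost without the 3 libraries low in small RNAs (0.02), with the macrophage score (0.05), the small-RNA class or the Y-linked transcripts as a covariate, at a mean of at least 5 FPKM and under TPM scaling. Without the 3 libraries rich in myeloid transcripts the median was 0.50. Without Shb-inactivated replicate 5 Rgs5 was 70.9 and 69.2 FPKM. Fibroblast genes did not pass (median -0.50, adjusted p 0.0509), with Col3a1 at 125 and 97.2 FPKM (98.3 and 97.2 without wild-type replicate 1) and Col1a1 at 57.4 and 38.1 FPKM (35.4 and 38.1 without wild-type replicate 1, 57.4 and 20.4 without Shb-inactivated replicate 6). They passed without wild-type replicate 3 (-0.86, adjusted p 0.00351) or Shb-inactivated replicates 2, 5 or 6 (-0.65, -0.63 and -0.75, adjusted p 0.0255, 0.0134 and 0.00323). They also passed with the melanoma score (-0.70, adjusted p 0.00453), the macrophage score (-0.77, adjusted p 2.65e-05), both (-0.52, adjusted p 0.000666), the replicate block (-0.89, adjusted p 2.19e-06) or library quality weights (-0.62, adjusted p 0.0214), under TPM and quantile scaling, with a pseudocount of 0.1 and with zeros of abundant genes as missing. The median was -0.27 without Shb-inactivated replicate 3 and -0.22 without the 3 libraries rich in myeloid transcripts. Erythroid genes did not pass (median -0.23, adjusted p 0.24), with Hbb-bs at 7.07 and 11.2 FPKM and Hba-a1 at 4.50 and 5.91 FPKM. Without Shb-inactivated replicate 2 these were 7.07 and 5.97, and 4.50 and 2.57 FPKM, and the list passed (-0.56, adjusted p 0.00147). It also passed without the 3 libraries low in small RNAs (-0.70, adjusted p 0.000108). The median turned without Shb-inactivated replicate 3 (0.03), without the 3 libraries rich in myeloid transcripts (0.27), with the melanoma score (0.09) and with both scores (0.15).

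**Figure D3:**
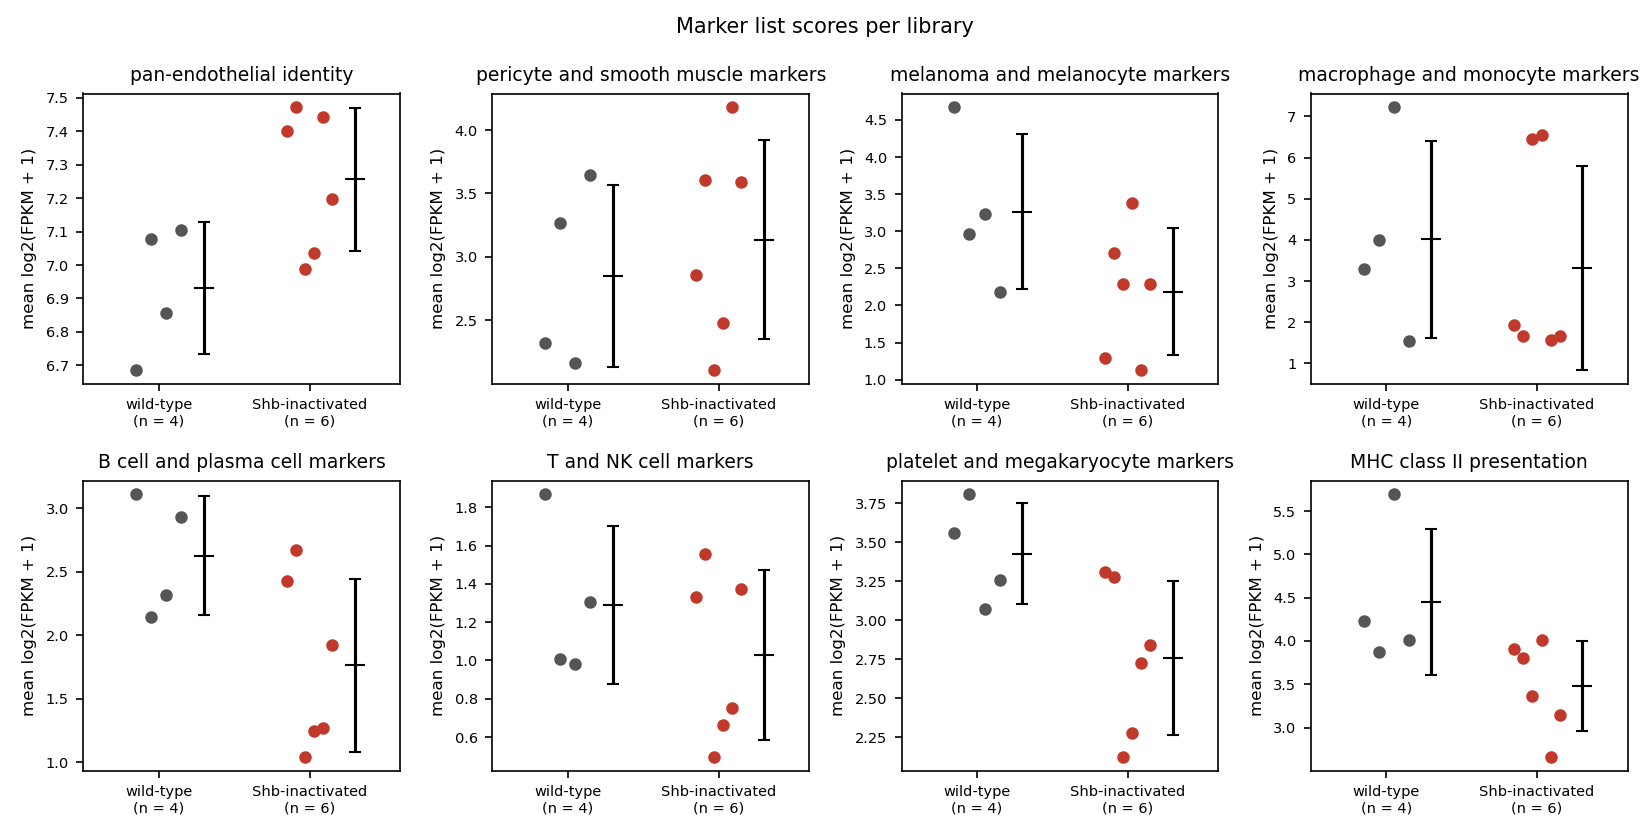
Mean log2(FPKM + 1) of 8 gene lists per library (points), with mean and SD (bars), for 4 wild-type and 6 Shb-inactivated libraries. The macrophage score was high in 3 libraries of both groups, and no score of a cell type passed its adjusted test.

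By the exact permutation test, none of 16 cell type scores differed past an adjusted p of 0.05 (smallest 0.356), and none had an unadjusted p under 0.05. The smallest exact p that 210 splits can give is 0.00476, so 1 score alone could not have passed the adjusted test. The B cell score differed by -0.86 (exact p = 0.0667), the platelet score by -0.67 (exact p = 0.0619) and the melanoma score by -1.08 (exact p = 0.119), or -0.61 without wild-type replicate 1. Neutrophil, keratinocyte, skeletal muscle, adipocyte and lung epithelium lists had fewer than 5 tested genes. Their score differences were -0.62, 0.0015, -0.0077, -0.04 and -0.09 (exact p from 0.152 to 0.995). The neutrophil, keratinocyte, skeletal muscle and lung epithelium differences were -0.03, -0.02, 0.05 and 0.06 without wild-type replicate 3. The keratinocyte difference was -0.06 without Shb-inactivated replicate 6, and the adipocyte difference -0.0096 without wild-type replicate 1. S100a9 and S100a8 were 139 and 3.53 FPKM, and 112 and 3.56 FPKM, with wild-type SDs of 267 and 215. Without wild-type replicate 3 they were 5.87 and 3.53, and 4.67 and 3.56 FPKM. Sfn was 4.67 and 3.61 FPKM, Krt10 0.228 and 0.462 (0.228 and 0.176 without Shb-inactivated replicate 6), Mylpf 1.39 and 0.905, Tnni2 0.483 and 0.465 (0.06 and 0.465 without wild-type replicate 3). Plin4 was 0.375 and 0.20 FPKM and Cidec 0.0725 and 0.04 FPKM, or 0.19 and 0.20 and 0.0133 and 0.04 without wild-type replicate 1. Lyz1 was 8.75 and 4.37 FPKM, and 0.563 and 4.37 without wild-type replicate 3. Without all 3 libraries rich in myeloid transcripts it was 0.563 and 0.0925 FPKM. Rtkn2 was 0.48 and 0.35 FPKM.

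Of the cell state lists, proliferation, ribosomal protein and mitochondrially encoded genes passed camera at the preset correlation, all lower. Proliferation genes had a median of -0.18, with Pcna at 134 and 141 FPKM and Cdk1 at 128 and 110.1 FPKM. Pcna turned without wild-type replicate 1 (149 and 141 FPKM) or Shb-inactivated replicate 3 (133.8 and 133.2 FPKM). Cdk1 turned without wild-type replicate 4 (103 and 110.1 FPKM). The proliferation list had an adjusted p of 0.00564, and an adjusted p = 0.627 with an estimated correlation. The call was lost without wild-type replicate 4 (median -0.03) or Shb-inactivated replicate 5 (median -0.05), and medians without wild-type replicate 3 and Shb-inactivated replicate 1 were -0.31 and -0.30. With the replicate block the median was 0.0021, and the call was lost there and with no filter. The median was -0.32 with library quality weights, -0.36 without the 3 libraries rich in myeloid transcripts and -0.37 without the 3 low in small RNAs. Ribosomal protein genes had a median of -0.06 (adjusted p 0.0122, and adjusted p = 0.627 with an estimated correlation), with Rps27 at 2539 and 2323 FPKM and Rps29 at 1881 and 1609 FPKM. That median ranged from -0.14 without wild-type replicate 1 to 0.0025 without wild-type replicate 4. The call was lost there and without wild-type replicate 2 or Shb-inactivated replicate 1 (both -0.03), with no filter and with the small-RNA class. The median was -0.16 with library quality weights, -0.13 with the melanoma score and -0.13 without the 3 libraries low in small RNAs. Mitochondrially encoded genes had a median of -0.41 and a mean of -0.12 (adjusted p 0.0142, and adjusted p = 0.565 with an estimated correlation). Without wild-type replicate 1, in which they made up 14.5% of all FPKM, the median was 0.05, and without the 3 libraries low in small RNAs it was 0.0088. It was 0.07 with both marker scores, -0.01 with the melanoma score and -0.09 with library quality weights. The call was lost in all of these and with no filter. The gene mt-Atp8 was 8819 and 6071 FPKM, and 6042 and 6071 FPKM without wild-type replicate 1. The gene mt-Co1 was listed at 0 in 6 libraries and was 15671, 4934, 5724 and 6631 FPKM in wild-type replicate 1 and Shb-inactivated replicates 1, 2 and 6. Hypoxia and glycolysis (median -0.02, adjusted p 0.215), the unfolded protein response (0.05, 0.365), nuclear-encoded oxidative phosphorylation (0.01, 0.652) and immediate early genes (0.18, 0.0609) did not pass. Immediate early genes passed without wild-type replicate 3 (0.50, adjusted p 1.35e-07), Shb-inactivated replicate 1 (0.23, adjusted p 0.0447) or 5 (0.22, adjusted p 0.00422), or the 3 libraries rich in myeloid transcripts (0.46, adjusted p 7.34e-06). They also passed with library quality weights (0.37), the melanoma score (0.32), the macrophage score (0.27), both (0.235) or the replicate block (0.27), with no filter and under median-of-ratios scaling. Without wild-type replicates 1 and 4 their median was 0.01 and 0.10. Oxidative phosphorylation genes turned and passed as lower without wild-type replicate 1 (-0.13, adjusted p 4.09e-05) or the 3 libraries low in small RNAs (-0.10, adjusted p 0.0113), with library quality weights (-0.10, adjusted p 0.000129), the melanoma score (-0.07, adjusted p 0.0315) or both scores (-0.10, adjusted p 0.00326), and under quantile normalization (-0.04, adjusted p 0.00245). Hypoxia genes passed as lower without Shb-inactivated replicate 5 (-0.08, adjusted p 0.0484) and under quantile normalization (-0.05, adjusted p 0.0211). Unfolded protein response genes passed as higher with the melanoma score (0.13, adjusted p 0.0419) and with both scores (0.10, adjusted p 0.0437), and their median turned without Shb-inactivated replicates 3 or 4 (-0.02 and -0.01). Gapdh was 660 and 681 FPKM, Pkm 666 and 658, Hspa5 681 and 787, and Calr 504 and 533 FPKM. Atp5b was 558 and 569 FPKM, Cox6c 292 and 301, Hspa8 1146 and 1330, and Fos 281 and 306 FPKM. Fos was 158 and 306 FPKM without wild-type replicate 3, and its direction turned without wild-type replicates 1, 2 or 4 (340, 308 and 318 against 306 FPKM) or Shb-inactivated replicates 3 or 4 (281 against 276 and 269 FPKM). Nuclear RNAs that mark library quality did not pass (adjusted p 0.469), with a median of -0.31 and a mean of 0.38. The median was -0.09 and -0.11 without wild-type replicate 1 and Shb-inactivated replicate 4. It was -0.0049 without the 3 libraries rich in myeloid transcripts, -0.02 without the 3 low in small RNAs, -0.63 with zeros of abundant genes as missing, 0.02 with no filter and 0.06 with library quality weights. Rpph1 was 8441 and 5146 FPKM, and Rn7sk was listed at 0 in wild-type replicate 4. It was 5734, 39330 and 32157 FPKM in wild-type replicates 1 to 3 and 8625, 16773, 30597, 9575, 31229 and 29122 FPKM in the inactivated libraries.

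Across the transcriptome, limma placed 0 of 12805 genes past an adjusted p of 0.05 (smallest 0.989). At an unadjusted p under 0.05 there were 442 genes, 216 higher and 226 lower, where 640.25 are expected by chance. The exact rank-sum test gave 0 genes and 375 unadjusted. The groups did not overlap in 92 genes, where chance gives 0.952%, or 122 genes. The 10 genes with the smallest p among those with higher values, none past the threshold, were Zfp521, Sox17, Tspan2, Fgd5, Mall, Rasd1, Mtus1, Tgfbr3, Pmepa1 and Dnm3. Zfp521, a zinc finger transcription factor, was 7.65 ± 1.17 and 11.6 ± 0.854 FPKM. Sox17 was 24.5 ± 3.27 and 36.1 ± 5.06 FPKM. Fgd5, an endothelial activator of Cdc42, was 43.0 ± 2.61 and 55.0 ± 3.85 FPKM, and Tgfbr3, the TGF-beta co-receptor betaglycan, was 4.95 ± 1.15 and 7.87 ± 1.34 FPKM. Those with lower values were Shb, Hist3h2bb-ps, Iglv3, Stat4, Terc, Snhg20, Setd6, Gpr171, Snord17 and Iglc2. Stat4, a transcription factor of interleukin-12 signalling in lymphocytes, was 4.20 ± 1.28 and 1.94 ± 0.431 FPKM. The RNA component of telomerase, Terc, was 8.73 ± 2.07 and 3.10 ± 2.04 FPKM, and Gpr171 was 7.42 ± 2.47 and 3.48 ± 1.05 FPKM. Immunoglobulin, histone and small nucleolar RNA genes have near-identical copies or are short, and their FPKM is uncertain.

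Over the gene lists, camera at the preset correlation placed 22 of 33 past an adjusted p of 0.05, 13 higher and 9 lower. With an estimated correlation, with fry and with exact permutation of the list scores, 0 passed (smallest adjusted p 0.292, 0.315 and 0.52). By exact permutation 1 list alone could not have passed over 39 lists. With each library left out in turn, 13 of the 22 kept their preset call. The count was 23 without the 3 libraries rich in myeloid transcripts and 18 without the 3 low in small RNAs, 3 against 4 libraries.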

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

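The tests of melanoma, macrophage, lymphocyte, myeloid and scaling explanations, and the count of other splits for single genes, were chosen after the values were seen. The count of other splits for gene lists was set before its result was seen.

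Of 276 combinations of a gene or list with a group, counted over both groups, 18 had 1 library far from the rest of its group, where chance gives about 1 in 20. The number given is that library's gap to the nearest other as a share of the group's range. In wild-type replicate 1, Tspan2 (0.962) and Cox6c (0.876) were low, and Snhg20 (0.843), Cidec (0.868), mt-Co1 (1), the mitochondrially encoded list (0.892) and the VEGF receptor list (0.870) were high. In wild-type replicate 3, H2-D1 (0.843), Tnni2 (0.888) and the interferon list (0.928) were high. In Shb-inactivated replicate 2, the tip cell list (0.733) and the basement membrane list (0.744) were high. Their scores were 8.36 and 6.83 there and 7.66 and 6.38 in wild-type replicate 1, the next highest library. These scores average all 23 genes of each list, but 21 and 20 passed the filter and entered the list medians. Which members raised the scores was not examined. In Shb-inactivated replicate 5, Pecam1 (0.744), Esm1 (0.676) and Gpihbp1 (0.638) were high and Igfbp3 (0.968) was listed at 0. In Shb-inactivated replicate 6, Krt10 (0.893) and the keratinocyte list (0.780) were high.

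The first pattern is the Shb transcript left after inactivation. The tables argue against macrophages as its main source, since at most 21.9% of the remaining Shb can scale with the macrophage markers in all 6 libraries, and at most 30.8% with any 1 left out. Melanoma cells stay open, since up to 61.5% can scale with their markers. Over the 6 libraries Shb followed the melanoma score with Pearson's r = 0.756 (exact permutation p = 0.0681) and Spearman's rho = 0.83 (exact p = 0.0583), both 0.136 adjusted over 4 tests. The relation rests on the 2 farthest libraries, since r was 0.25 without them, and for the macrophage score r was 0.20 (exact p = 0.671) and rho 0.60 (exact p = 0.242). Incomplete recombination and exons outside a deleted part were not tested.

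The second pattern is the higher level of endothelial transcripts. The tables argue against scaling, since at least 90.2% of the pan-endothelial score difference stayed under median-of-ratios, quantile and TPM scaling. A lower share of melanoma cells cannot be told apart from it, because with the melanoma score in the model the difference went from 0.32 (SE 0.13) to 0.15 (SE 0.12). An effect of Shb loss on endothelium stays open as a hypothesis. For the count of lists, 2 of 100 splits of the libraries, the real one included, gave at least 22 lists, so few of the drawn groupings called as many. With an estimated correlation, fry or exact permutation 0 lists passed, so a shift of the lists is not established. The highest of the other splits also gave 22 and the median split gave 13, so the preset correlation calls many lists for other groupings too.

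The third pattern is the lower level of B cell and plasma cell transcripts. An equal loss of all lymphocytes would move T and NK cell markers alike, but the B cell score minus theirs differed by -0.60 (SE 0.17, exact permutation p = 0.00952). T and NK cell transcripts are low, and a pseudocount of 1 shrinks differences among low values, so the comparison was repeated with the tested members only and a pseudocount of 0.1. This check was added after the first result was seen. The difference was -0.63 (SE 0.20, exact permutation p = 0.0143), with T and NK cell transcripts also lower, by -0.61. Neither exact p was adjusted for picking the B cell list after its values were seen. A loss of all lymphocytes that is larger for B cells is not excluded. An unequal share of myeloid cells is argued against too, since with the macrophage score in the model the B cell difference was -0.98 (SE 0.32). The score itself differed by -0.86 (SE 0.39) and did not pass its exact test. Fewer B cells in or beside the tumours, or less carry-over of them in the sort, stay open and were not tested.

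For single genes the real grouping gave 0. Any split gives at least that many, so the count of splits says nothing about chance there. The highest of the other splits gave 1061 genes, and 10 of them gave at least 1. That split put the 3 libraries rich in myeloid transcripts in 1 group, which points to a structure of the samples that the study groups do not follow.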

How the results depend on the processing

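The count of genes past the threshold was 0 under each of 29 alternatives, and so was the count of cell type scores under its 17. The rank-sum alternative could pass only if a large share of genes separated the groups fully, so its 0 has no weight. For the scores, the replicate block rests on 4 pairs and could not pass at all. The other score alternatives could pass only with more than 1 score near the smallest possible p. Shb kept its direction and an unadjusted p under 0.05 in the 28 alternatives that tested it, from -1.92 to -0.54, and from -1.36 to -1.10 with each library left out. Shb was not tested at a mean of at least 5 FPKM. The count of lists was 16 to 23 in the camera alternatives at the preset correlation. It was 0 with an estimated correlation, 0 with fry and 0 by exact permutation, which allow for genes that vary together. Replicate numbers 1 to 4 occur in both groups, and the labels do not say what a shared number means. The correlations of deviations were 0.44, -0.32, 0.71 and -0.55 for numbers 1 to 4. They were higher between wild-type replicate 1 and Shb-inactivated replicate 2 (0.60), and between wild-type replicate 3 and Shb-inactivated replicate 4 (0.75). These values do not settle whether equal numbers mark pairs. With the replicate block there were 0 genes, 19 lists and a Shb log2 fold change of -1.14. Library totals are unknown, which limits low genes most.

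Of 2658 values of named genes under alternatives, 2647 moved by less than the spread between replicates or kept their call, 7 moved by more and 4 reversed. The sign turned in 141 of the 2658. No gene passed in any setting, so no call could be lost. For genes given only as values, a turn of sign was not counted as a reversal. The 2647 are therefore a weak measure of stability. Of 986 list medians, 779 stayed, 114 lost and 40 gained a call, and 53 reversed, of which 6 passed in the turned direction. A reversal was read from the sign of the list's median, a choice made after a first look at the results. Read from the direction of the set test there would be 44, and 71 by either. The cause was not tested. With library quality weights the reversed values were Itgam 0.035, chemokines 0.19, macrophage 0.22, pericyte -0.22, oxidative phosphorylation -0.10 and nuclear RNAs 0.064. With the melanoma score they were Itgam 0.21, chemokines 0.25, macrophage 0.62, erythroid 0.087, pericyte -0.26, hypoxia 0.048 and oxidative phosphorylation -0.068. A list tested with its own score in the model must come out near 0, so the macrophage values with the macrophage score or both scores, and the lost melanoma calls with theirs, say nothing of stability. With the macrophage score, chemokines were 0.13 and macrophage 0.020. With both scores, macrophage was 0.058, erythroid 0.15, pericyte -0.16, hypoxia 0.031, oxidative phosphorylation -0.098 and mitochondrially encoded genes 0.075. With the replicate block, chemokines were 0.047, macrophage 0.26, pericyte -0.10 and proliferation 0.00206. With no filter, checkpoints were -0.10 and nuclear RNAs 0.020. Hypoxia was 0.032 under TPM scaling, and oxidative phosphorylation was -0.022, -0.037 and -0.00165 under median-of-ratios scaling, quantile normalization and the Y-linked covariate. Without the 3 libraries low in small RNAs, Shf was -0.053, Notch -0.013, TGF-beta -0.00422, checkpoints -0.053, oxidative phosphorylation -0.097 and mitochondrially encoded genes 0.00881. Without the 3 rich in myeloid transcripts, erythroid was 0.27, hypoxia 0.046 and the unfolded protein response -0.047. With each library left out, the ranges were -1.80 to 0.38 for Itgam, -0.13 to 0.068 for oxidative phosphorylation, -0.56 to 0.054 for mitochondrially encoded genes and -0.16 to 0.38 for checkpoints. They were -0.912 to 0.48 for chemokines, -1.61 to 0.38 for macrophage, -0.11 to 0.017 for hypoxia and -0.14 to 0.00255 for ribosomal genes. For TGF-beta, erythroid and unfolded protein response genes they were -0.000286 to 0.16, -0.56 to 0.029 and -0.020 to 0.095.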

Other observations

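Transcripts of the sex chromosomes set 2 libraries apart. Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, were all at 0 FPKM in Shb-inactivated replicate 2, and Xist, the RNA that coats the inactive X chromosome, was 32.9 FPKM there. In wild-type replicate 1, Ddx3y and Eif2s3y were at 0, Kdm5d was 0.01, Uty was 0.18 and Xist was 0.13 FPKM, so neither Y-linked transcripts nor Xist stood out. In the other 8 libraries Ddx3y was 46.5 to 85.5 FPKM and Xist at most 0.01. These genes were chosen after their values were seen.

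Small RNAs set 3 libraries apart. Of 47 small nucleolar and related RNA genes, 66.0% were listed at 0 in wild-type replicate 1, 63.8% in Shb-inactivated replicate 1 and 66.0% in replicate 2. The share was 17.0% to 40.4% in the other libraries. The first principal component of the tested genes held 43.5% of the variance, and the 3 libraries with the most Itgam had its 3 highest values.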
